A study of Mus musculus with 18 samples.

How the data were processed

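RNA from 3T3-L1 cells was measured by RNA sequencing in 18 libraries, 3 for each of 6 groups. The groups combine control (CTL), MLKL-/- or RIPK3-/- cells with the labels J0 (undifferentiated) and J7 (differentiated). Groups follow the sample titles, which are also the names used in the deposited tables. In the 6 J7 knockout samples the genotype characteristic names the other knockout, and J7_MLKL and J7_RIPK3 are therefore to be read as title names. The labels give no batch and do not say whether the 3 libraries of a group are separate cultures, so the p-values measure only the spread between these samples.

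The submitters' notes name FastQC 0.11.9, HISAT2, featureCounts 1.5.0-p3, DESeq2 and the mouse build mm10. Each of the 7 deposited comparison tables gives, per library, the raw read count of each gene. The same deposited tables give the authors' normalised count (signal), which is the count divided by 1 size factor per library and table. They also give the authors' FPKM values, scaled by gene length and library total. The authors' log2 fold change, first-named group over second, stands beside the authors' p-value and adjusted p-value for each gene. The deposited tables further give mm10 coordinates and, in the other columns, a gene length in bases. Each table holds only genes with the authors' adjusted p under 0.05, so every count of genes below comes from a preselected set. Of the 21 deposited tables, the 7 pathway tables were read for the authors' leading pathways, and the gene ontology tables were not analysed here.

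Raw counts were joined by Ensembl gene identifier over all tables that list the same library. The join gave 15194 genes, of which 12666 are protein-coding and 2802 have counts in all 18 libraries. Of 88950 library-by-gene counts that occur in more than 1 table, 0 differed. Library totals of 20.2 to 36.9 M reads were recovered from the count, FPKM and length columns and were used as library sizes, because the listed genes hold only part of each library. Antisense or overlapping transcription cannot be separated from a gene's own reads in these tables. The reference annotation used here is on a later mouse build, so no coordinate was taken from it, and it served only for transcript length and GC content of 15011 genes (98.8%).

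Each comparison was fitted on genes with counts in every group compared, with edgeR 4.0.16 (filterByExpr, TMM factors on the recovered totals, quasi-likelihood F test) in R 4.3.3. P-values were adjusted by Benjamini-Hochberg within a comparison, and genes with adjusted p under 0.05 are called higher or lower. Adjusted p-values of single genes are from this test, and standard errors (SE) of log2 fold changes were derived from its F statistic. TMM factors take most genes as unchanged, but 39 to 97.8% of the preselected genes tested in a comparison were called. The split of calls into higher and lower therefore depends on the scaling and is not a result by itself. Levels are CPM (reads scaled to the library total, per-million), given as mean ± SD over 3 libraries. Folds are ratios of a group's pooled reads over its pooled totals, without TMM factors, so they can differ slightly from the log2 fold changes. Where a group had 0 reads, the fold is a lower bound against a floor of 3 reads over the group. Where it had 1 to 3 reads, the ratio is given with its exact 95% counting interval. Floors and intervals cover counting error only. The design covers 7 pairs of groups with a deposited table and the direct contrasts of both knockouts at J0 and J7. It also covers, for each knockout, the difference between its J7 minus J0 change and that of CTL.

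Gene lists, the rule for named genes, the tests and the first set of alternatives were fixed before the data were examined. The lists cover adipogenic transcription factors, adipocyte markers, fatty acid and triglyceride synthesis, lipid droplet and lipolysis, fatty acid oxidation, brown and thermogenic genes and insulin signalling. They also cover Wnt ligands, Wnt targets and regulators, preadipocyte and mesenchymal progenitor genes, fibrillar matrix, basement membrane, contractile and YAP/SRF targets and cell cycle. The remaining lists are necroptosis machinery, apoptosis and pyroptosis, inflammatory NF-kB targets, interferon response, p53 targets, unfolded protein and integrated stress response, cholesterol synthesis, glycolysis and hypoxia, respiratory chain and TCA cycle, antioxidant Nrf2 targets, immediate early genes, and markers of skeletal muscle, osteoblast, chondrocyte, macrophage, endothelium and epithelium. For each list, higher against lower calls were compared with those of all other called genes by a two-sided Fisher exact test, adjusted over the lists of a comparison. This test treats genes as independent. Competitive and rotation set tests were not used, because the tables are preselected on the comparisons.

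Named genes are protein-coding genes chosen by the rule. It takes Mlkl and Ripk3, then the 5 highest and 5 lowest log2 fold changes among called genes whose groups do not overlap and whose higher group has a mean of at least 100 counts. It adds up to 4 called members of each list with the largest changes at the same minimum, uncalled members by level, and Pparg, Cebpa, Adipoq, Fabp4, Plin1, Wnt10b and Dlk1. For the differences of changes, non-overlap was asked of the J7 groups. For 3 libraries against 3, chance alone leaves 10% of genes without overlap.

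Agreement of both knockouts against shared controls was set beside 20 simulated draws of unchanged groups against the same controls. The tests were also run on simulated data with planted changes in 200 genes. There, 2.3 to 8.5% of calls were false, and planted 2-fold changes were found in 38% (J7_MLKL against J7_CTL) to 98% (J0_RIPK3 against J0_CTL) of cases. All other simulated genes were unchanged, whereas 39 to 97.8% of the real, preselected genes were called. These rates therefore do not give the error or detection rates of the real tests. Of 1000 random lists of 20 genes, drawn in J0_RIPK3 against J0_CTL only, 4.5% had a Fisher p under 0.05. Alternatives were RLE size factors, total reads only, no filter on low counts, a mean of at least 50 counts and the DESeq2 1.42.0 Wald test. The RLE factors, the kind DESeq2 uses, were computed in edgeR and are called DESeq2 size factors in the text. The Wald test kept the TMM factors. Other alternatives were a fold limit, all 6 groups in 1 fit, the replicate number as a block, and leaving out each library. Added after the data were seen were the authors' size factors, adjustment over the authors' number of genes, and leaving out the 2 MLKL libraries that stand apart from their groups. For the gene lists, total reads only, no filter, the DESeq2 Wald test and the fold limit were also added then. Further work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.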

Results

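RNA was sequenced from 3T3-L1 cells, a mouse fibroblast line that becomes adipocytes in culture. Control cells (CTL) and cells labelled as knockouts of Mlkl (MLKL-/-) or Ripk3 (RIPK3-/-) were each taken undifferentiated (J0) or differentiated (J7), with 3 libraries in each of 6 groups. MLKL is the pseudokinase that permeabilises the plasma membrane in necroptosis, and RIPK3 is the kinase that activates it. Library totals in M reads were 34.8, 29.2 and 24.8 in J0_CTL, 23.2, 28.4 and 25.9 in J0_MLKL, and 25.4, 22.9 and 36.9 in J0_RIPK3. At J7 they were 24.1, 24.6 and 26.8 in J7_CTL, 25.9, 21.7 and 26.4 in J7_MLKL, and 24.0, 20.2 and 26.5 in J7_RIPK3. The deposited tables list only genes with the authors' adjusted p under 0.05, and the listed genes held 90.0 to 98.4% of the reads of CTL and RIPK3 libraries. They held 29.3 to 30.4% of J0_MLKL reads and 53.5 to 54.5% of J7_MLKL reads, so MLKL comparisons rest on fewer and more strongly selected genes. Group names follow the sample titles. For the 6 J7 knockout samples the genotype characteristic names the other knockout. MLKL-/- and RIPK3-/- cells at J7 are therefore so called below by their titles alone.

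Both target transcripts were still read in every library. Mlkl (ENSMUSG00000012519, chromosome 8, 111311797 to 111338177, mm10) stood at 18.9 ± 0.793 CPM (SD, n = 3) in J0_CTL, 8.05 ± 1.45 in J0_MLKL and 16.0 ± 1.62 in J0_RIPK3. Its J7 levels were 26.3 ± 1.10 CPM in J7_CTL, 15.1 ± 1.24 in J7_MLKL and 29.1 ± 2.94 in J7_RIPK3. Against CTL, Mlkl fell in J0_MLKL (log2 fold change -1.20, adjusted p 0.000137) and J7_MLKL (-0.70, adjusted p 0.00122). It fell less in J0_RIPK3 (-0.25, adjusted p 0.00872), and in J7_RIPK3 its value was 0.16 (adjusted p 0.0502). Ripk3 (ENSMUSG00000022221, chromosome 14, 55784995 to 55788865, mm10) stood at 18.2 ± 1.40 CPM in J0_CTL, 7.45 ± 1.87 in J0_MLKL and 15.9 ± 1.31 in J0_RIPK3. At J7, Ripk3 had 18.3 ± 0.842 CPM in J7_CTL, 9.23 ± 2.40 in J7_MLKL and 10.9 ± 0.750 in J7_RIPK3. Ripk3 fell against CTL in J0_MLKL (-1.25, adjusted p 0.00038), J7_MLKL (-0.88, adjusted p 0.00509), J0_RIPK3 (-0.22, adjusted p 0.0216) and J7_RIPK3 (-0.73, adjusted p 2.44e-07). A small deletion or insertion need not lower a transcript, so these levels do not settle which gene was edited in which group.

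The comparison of J7_CTL with J0_CTL asks what differentiation changed in control cells. Adipocyte genes rose, some from near absence: Adipoq, which encodes the hormone adiponectin, reached 1756 ± 60.6 CPM (SD, n = 3) from 0 reads, at least 52000-fold higher. The fatty acid carrier Fabp4 rose 1290-fold, from 6.05 ± 0.287 to 7800 ± 268 CPM. Pparg, the nuclear receptor that drives adipogenesis, rose 18.6-fold (log2 4.17 ± 0.04 SE), and its partner Cebpa rose 23.5-fold. All 24 tested adipocyte markers rose (Fisher exact adjusted p 3.65e-06), and 12 of 13 adipogenic transcription factors did (0.00168 by the exact test). Among the latter, Nr1h3, the liver X receptor, rose 43.2-fold, while Cebpd was at 80.8 against 78.8 CPM (adjusted p 0.821). Lipid synthesis rose in 14 of 15 members (exact p 0.00302), with the desaturase Scd1 up 81.8-fold and the triglyceride enzyme Dgat2 up 46.6-fold. All 14 lipid droplet and lipolysis genes rose (exact p 0.000539), among them the droplet coat gene Plin1, 10300-fold higher, and the lipase inhibitor G0s2, 2840-fold higher. In insulin signalling, 8 of 9 rose (exact p 0.0161), led by the glucose transporter gene Slc2a4 (1470-fold), and fatty acid oxidation rose in 13 of 15 (exact p 0.0161), with the peroxisomal gene Pex11a up 13.3-fold.

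Metabolic lists rose with differentiation in CTL and progenitor, matrix and interferon lists fell. All 20 respiratory chain and TCA cycle genes rose (Fisher exact adjusted p 1.96e-05), with Idh3a, a TCA cycle dehydrogenase subunit, 9.49-fold higher. All 16 glycolysis and hypoxia genes (exact p 0.000188), all 17 cholesterol genes (exact p 0.000118) and all 13 genes of the unfolded protein and integrated stress response (exact p 0.000943) rose. Examples are the hexokinase gene Hk2 (30.6-fold), the sterol sensor Insig1 (8.6-fold) and the stress transcription factor Atf3 (31.1-fold). All 14 preadipocyte and mesenchymal progenitor genes fell (exact p 0.000285), for example the surface antigen Thy1 by a log2 fold change of -3.48 ± 0.04 (SE) and Gata2, a repressor of adipogenesis, by -3.32 ± 0.12. Fibrillar matrix fell in 17 of 21 (exact p 0.00973), with Col12a1 18.5-fold lower and the collagen crosslinker Lox 9.39-fold lower. Contractile and YAP/SRF targets fell in 11 of 13 (exact p 0.00906), with the smooth muscle actin gene Acta2 8.62-fold lower. All 19 interferon-response genes fell (exact p 1.96e-05): the antiviral genes Ifit1, Oasl2 and Mx1 were 112-fold, 84.3-fold and 77.9-fold lower. Of the p53 targets, 13 of 15 fell (exact p 0.00973), with the receptor gene Eda2r 8.29-fold and the death receptor gene Fas 7.20-fold lower.

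No directional excess passed the test in the other lists of J7_CTL against J0_CTL. Basement membrane had 8 higher and 1 lower (Fisher exact adjusted p 0.0712), with Col15a1 33.9-fold higher. The result became 0.0406 without J7_CTL 1, 0.0406 without J7_CTL 2, 0.0407 without J7_CTL 3 and 0.0422 with total reads only, which for lists was chosen after the data were seen. Wnt ligands had 0 higher and 5 lower (exact p 0.0585, and 0.0492 with the authors' size factors), with Wnt4 7.69-fold lower and Wnt5a 4.45-fold lower. Wnt10b, an inhibitor of adipogenesis, had 2 reads over the J7 libraries and a ratio of 40 (95% counting interval 11.1 to 331). Cell cycle had 10 higher and 11 lower (exact p 0.831), with the cyclin gene Ccne2 4.5-fold higher and Ccnb2 2.65-fold lower. That count turned to 12 higher and 9 lower with total reads only, 13 and 9 with the authors' size factors, and 10 and 9 with DESeq2 size factors. Exact p-values were 0.585 for brown and thermogenic genes, 0.749 for Wnt targets and regulators, 0.533 for necroptosis machinery, 0.2 for apoptosis and pyroptosis, 0.542 for NF-kB targets, 0.63 for antioxidant genes and 0.63 for immediate early genes. For markers of other cell types the exact p was 0.62 in skeletal muscle, 0.585 in osteoblast, 0.733 in chondrocyte, 0.542 in macrophage, 0.689 in endothelium and 0.204 in epithelium, with all 4 tested genes higher. By edgeR, 11555 of 12055 tested genes were called, 5816 higher and 5739 lower, and the authors listed 12218. With p-values adjusted over the list alone, the number called was the same in every list except cell cycle (19 in place of 21).

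**Figure D1:**
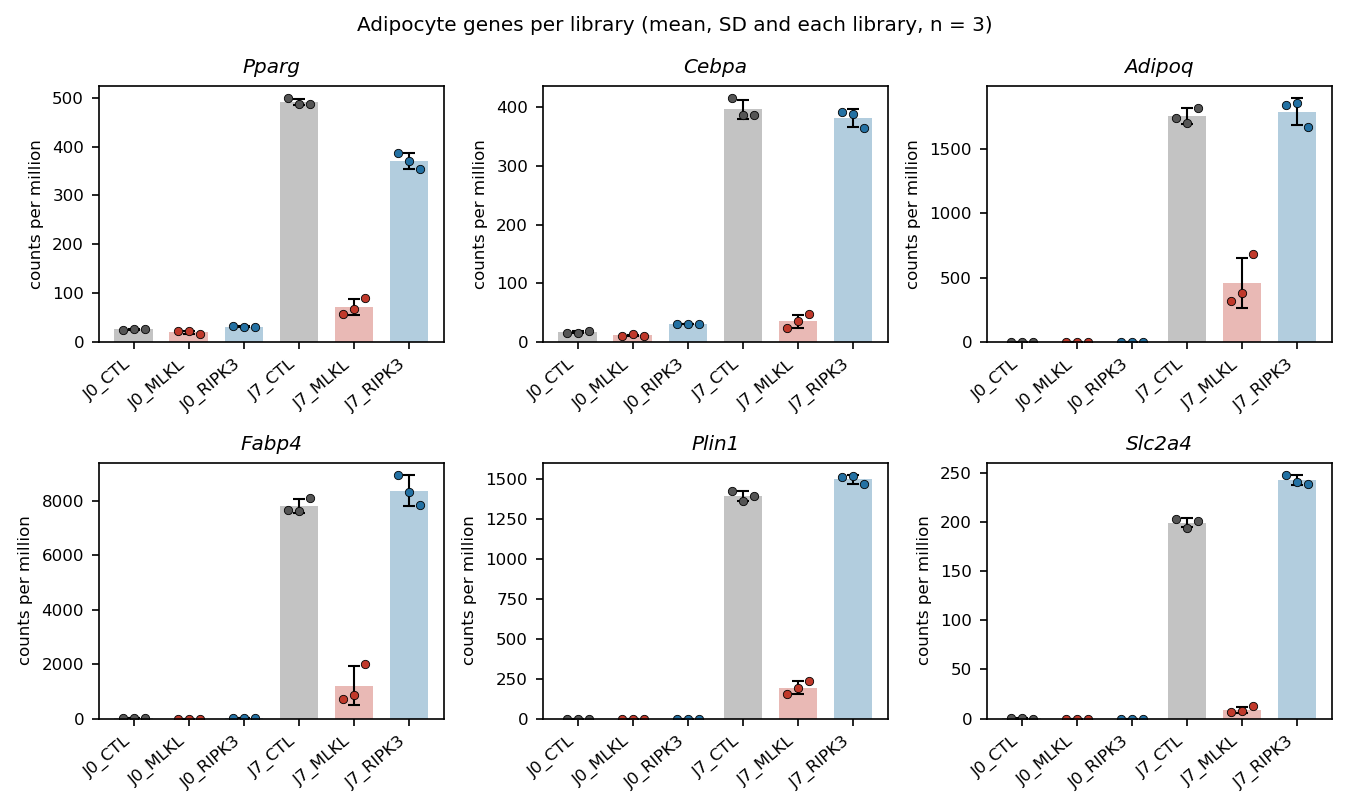
CPM of 6 adipocyte genes in each library, with bars for group means, error bars for the SD and points for the 3 libraries of each group. Levels are near 0 at J0 for Adipoq, Fabp4, Plin1 and Slc2a4, and at J7 each gene is lower in J7_MLKL than in J7_CTL, for example 71.2 against 491 for Pparg.

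The comparison of J7_RIPK3 with J0_RIPK3 asks the same of RIPK3-/- cells. Adipoq rose to 1791 ± 106 CPM (SD, n = 3), and the hormone gene Retn rose at least 10900-fold from 0 reads. Pparg rose 11.7-fold (log2 3.52 ± 0.04 SE), Cebpa 12.5-fold and Fabp4 966-fold. All 24 adipocyte markers rose (Fisher exact adjusted p 3.67e-06), as did 15 of 16 lipid synthesis genes (exact p 0.00161), all 14 droplet genes (exact p 5e-04), 12 of 14 oxidation genes (exact p 0.0286), all 8 insulin signalling genes (exact p 0.0186) and 11 of 13 adipogenic factors (exact p 0.0464). Cidea, a droplet gene of thermogenic adipocytes, rose at least 1840-fold, and Pck1, an enzyme of glyceroneogenesis, at least 3150-fold. Cell cycle fell in 24 of 26 members (exact p 4.93e-05): the proliferation marker Mki67 was 6.08-fold lower, the mitotic kinase Plk1 5.87-fold and the cyclin Ccna2 5.72-fold. All 15 progenitor genes fell (exact p 0.000157), with Pdgfra 7.41-fold lower, as did 18 of 21 matrix genes (exact p 0.00219), with the matricellular gene Postn 16.1-fold lower. Contractile genes fell in 13 of 15 (exact p 0.0101), with Acta2 17.6-fold lower, and interferon genes in 16 of 18 (exact p 5e-04), with Oasl2 52.4-fold lower. All 20 respiratory genes (exact p 2.94e-05), all 16 glycolysis genes (exact p 0.000157), all 16 cholesterol genes (exact p 0.000157) and all 13 stress-response genes (exact p 0.00084) rose, with the kinase inhibitor Trib3 17.0-fold higher. Dlk1, a preadipocyte marker, fell from 0.817 ± 0.231 CPM to 0 reads, at least 20.2-fold lower, and the interleukin receptor Il1rl1 fell 447-fold. Brown genes had 5 higher and 1 lower (exact p 0.339, and 5 and 0 with 0.0476 at an absolute log2 fold change over 1). Jun was at 100 against 102 CPM (adjusted p 0.208). By edgeR, 11533 of 11798 tested genes were called, 5813 higher and 5720 lower, beside 12268 listed by the authors. When adjusted over the list alone, each list had the same number called.

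The comparison of J7_MLKL with J0_MLKL asks the same of MLKL-/- cells. Adipocyte genes rose here too: Adipoq reached 463 ± 194 CPM (SD, n = 3) from 0 reads, at least 12100-fold higher, and the fatty acid transporter Cd36 rose at least 2960-fold. Fabp4 rose to 723, 883 and 2018 CPM in J7_MLKL 1, 2 and 3, so its 984-fold rise was lower by over 1.5 times without J7_MLKL 3. Pparg rose 3.49-fold (log2 1.77 ± 0.20 SE, adjusted p 0.000731) and Cebpa 3.13-fold. All 23 tested adipocyte markers rose (Fisher exact adjusted p 3.15e-05), and 9 of 11 lipid droplet genes did (exact p 0.0463), with Plin1 at 193 ± 41.2 CPM. The droplet result was 0.0528 with total reads only and 0.121 without J7_MLKL 2. Interferon genes rose in 16 of 18 (exact p 0.00075): Oasl2 was 6.6-fold, Ifit3 4.77-fold, Ifit1 4.67-fold and the guanylate-binding protein gene Gbp3 4.46-fold higher. The library J7_MLKL 3 stood apart from the other J7_MLKL libraries and J0_MLKL 2 from the other J0_MLKL libraries. Without both, 23 adipocyte markers, 17 interferon genes and 9 droplet genes rose. Adipogenic factors rose in 7 of 9 (exact p 0.0865, and 0.0469 without both libraries), with Nr1h3 6.56-fold higher, and cholesterol genes fell in 6 of 7 (exact p 0.073, and 0.0469 without both). Lipid synthesis had 10 higher and 1 lower (exact p 0.0835), with Scd1 4.55-fold higher, and progenitor genes had 0 higher and 5 lower of 8 tested (exact p 0.0904), with Gata2 2.64-fold and Thy1 2.51-fold lower. Among other genes, the growth regulator Cyr61 rose 4.83-fold, Col15a1 14.7-fold and the immediate early gene Zfp36 3.75-fold. The cell cycle inhibitor Cdkn1a fell 2.85-fold, Mfap4, a microfibril protein gene, 14.9-fold, and the cation channel gene Trpm5 12.2-fold. By edgeR, 2051 of 3075 tested genes were called, 1102 higher and 949 lower, and the authors listed 1891. Adjusted over the list alone, 17 interferon genes were called in place of 16, with no change in the other lists.

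The comparison of J0_MLKL with J0_CTL asks what differed in MLKL-/- cells before differentiation. Interferon-response genes fell in 16 of 18 tested (Fisher exact adjusted p 0.001), among them the RNA sensor Ifih1, 20.5-fold lower, the RNase activator Oas1a, 19.4-fold lower, and Ifit1, 4.82-fold lower at 7.36 ± 0.122 against 35.5 ± 4.60 CPM (SD, n = 3). Mx1 stood at 3.56 against 5.25 CPM (adjusted p 0.0579, called lower without J0_CTL 2 or J0_MLKL 3). Fabp4 fell 4.83-fold (log2 -2.24 ± 0.19 SE), Cebpa by -0.54 and Pparg by -0.34 on the log2 scale (adjusted p 0.0219, not called without J0_CTL 2, J0_CTL 3 or J0_MLKL 3). The largest rises included the BMP antagonist Chrdl1 (87.1-fold), the potassium channel gene Kcnc2 (65.0-fold) and Olfm2, which encodes a secreted glycoprotein (19.7-fold). The largest falls included the adenylate cyclase gene Adcy1 (112-fold), the transcription factor gene Foxp2 (59.9-fold), the dystrophin gene Dmd (51.0-fold) and the metalloprotease inhibitor Timp3 (39.4-fold). Of the basement membrane genes, Col15a1 fell 15.9-fold, Nid2 4.16-fold and Col18a1 2.59-fold, with 3 higher and 3 lower in the list (exact p 1). Wnt6 rose 6.0-fold and Wnt10b 2.02-fold, and all 5 tested Wnt ligands were called higher (exact p 0.263). Among p53 targets, with 1 higher and 10 lower (exact p 0.181), Trp53inp1 fell 2.73-fold and the ubiquitin ligase gene Mdm2 rose 2.24-fold. Acta2 rose 2.17-fold and the tropomyosin gene Tpm1 2.11-fold, with 4 contractile genes higher and 0 lower (exact p 0.409). The complement gene C3 rose 2.62-fold, and the lysozyme gene Lyz2 fell 2.99-fold. By edgeR, 3196 of 3824 tested genes were called, 1545 higher and 1651 lower, beside 3055 listed by the authors. Only the interferon list passed, also without the library J0_MLKL 2, which stood apart (exact p 0.000986). With p-values adjusted over the list alone, fatty acid oxidation had 3 called in place of 2, necroptosis machinery 3 in place of 2 and immediate early genes 4 in place of 5.

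The comparison of J0_RIPK3 with J0_CTL asks what differed in RIPK3-/- cells before differentiation. All 26 cell cycle genes rose (Fisher exact adjusted p 9.21e-07): Mki67 went from 33.7 ± 2.65 to 87.3 ± 2.78 CPM (SD, n = 3), 2.58-fold higher, with Plk1 2.7-fold, Ccna2 2.59-fold and the mitotic kinase Aurka 2.57-fold higher. All 17 cholesterol genes rose (exact p 0.000155), led by the demethylase gene Cyp51 (2.86-fold), with Idi1 1.93-fold and Insig1 1.84-fold higher. Interferon genes fell in 18 of 19 (exact p 4.17e-05): Oas1a was 7.97-fold, Ifih1 6.06-fold, Mx1 4.53-fold and Ifit1 4.35-fold lower, while Ifit2 stood at 24.6 against 26.2 CPM (adjusted p 0.137). The largest single changes were rises of Kcnc2 (14.9-fold) and the glutamate receptor gene Gria3 (9.03-fold) and falls of Adcy1 (124-fold, larger without J0_RIPK3 3) and the guanylate-binding protein gene Gbp9 (20.3-fold). Of 11 adipogenic factors 4 were higher and 3 lower (exact p 1), with Ebf2 3.02-fold, Cebpa 1.81-fold and Pparg 1.19-fold higher, and Fabp4 rose 1.43-fold. Thy1 fell 2.21-fold and Col15a1 4.53-fold, while the elastin gene Eln rose 3.19-fold and the desaturase Scd1 1.77-fold. Mdm2 rose 1.65-fold. Genes of the stress response had 0 higher and 7 lower of 13 tested (exact p 0.0521), with Trib3 1.49-fold lower. This passed in 11 alternatives, among them total reads only (0.0254), the replicate block (0.0472) and a mean of at least 50 counts (0.0489), and without J0_CTL 1 (0.0459), J0_CTL 2 (0.0481), J0_RIPK3 1 (0.0473), J0_RIPK3 2 (0.0473) or J0_RIPK3 3 (0.0457). Oxidation had 7 higher and 0 lower (exact p 0.0939, 0.0472 with the replicate block, 0.0459 without J0_CTL 1 and 0.0457 without J0_RIPK3 3), antioxidant genes 9 higher and 1 lower (exact p 0.108) and matrix 11 higher and 3 lower (exact p 0.247). By edgeR, 6159 of 11044 tested genes were called, 3129 higher and 3030 lower (3401 and 2717 with total reads only), beside 5167 listed by the authors. When adjusted over the list alone, oxidation had 8 called in place of 7, respiratory chain 7 in place of 8, antioxidant genes 11 in place of 10 and epithelium 2 in place of 1.

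**Figure D2:**
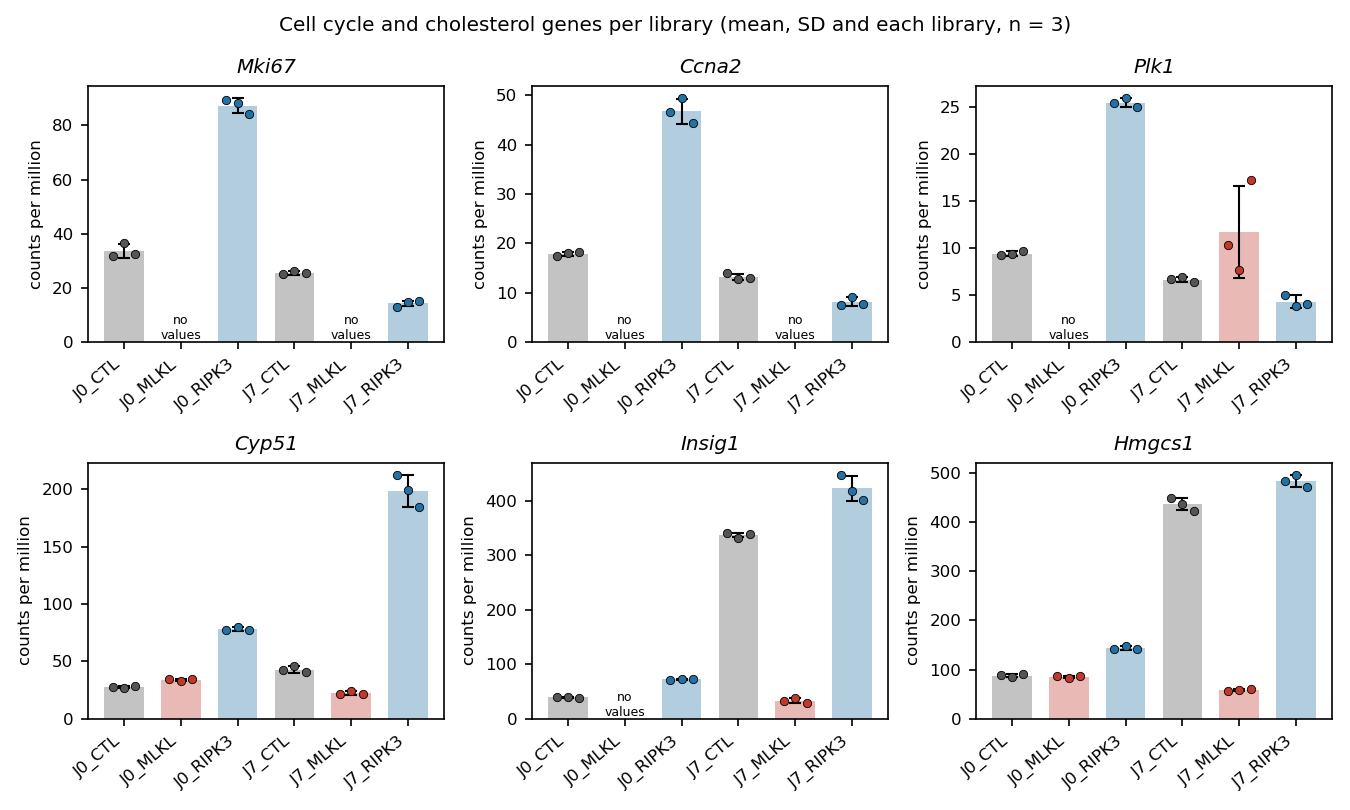
CPM of 3 cell cycle genes (Mki67, Ccna2, Plk1) and 3 cholesterol genes (Cyp51, Insig1, Hmgcs1) in each library, with bars for group means, error bars for the SD and points for the 3 libraries of a group. Mki67 is at 87.3 in J0_RIPK3 against 33.7 in J0_CTL, and groups marked as having no values are those in which the deposited tables do not list the gene.

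The comparison of J7_MLKL with J7_CTL asks how differentiated MLKL-/- cells differed from differentiated control cells. Adipogenic regulators were lower: Pparg stood at 71.2 ± 16.5 against 491 ± 6.87 CPM (SD, n = 3), 6.86-fold lower (log2 -2.68 ± 0.18 SE), Cebpa was 11-fold lower and Klf15, a metabolic regulator, 41.3-fold lower. Adipoq fell 3.75-fold (adjusted p 0.0012), Fabp4 6.34-fold (more without J7_MLKL 3), Plin1 7.20-fold and Slc2a4 22.0-fold. Adipocyte markers fell in 22 of 24 (Fisher exact adjusted p 5.97e-05), adipogenic factors in 9 of 10 (exact p 0.0262), droplet genes in all 14 (exact p 0.000196) and insulin signalling in all 7 (exact p 0.0188). Lipid synthesis fell in 14 of 15 (exact p 0.000196), with Scd1 20.4-fold and Dgat2 11.3-fold lower, and fatty acid oxidation in 11 of 13 (exact p 0.0268), with Pex11a 3.98-fold lower and the coactivator Ppargc1a 3.54-fold higher. Acacb was at 41.3 against 43.4 CPM (adjusted p 0.827). All 17 cholesterol genes (exact p 7.95e-05), all 15 glycolysis and hypoxia genes (exact p 0.000172), 14 of 15 respiratory genes (exact p 0.000196) and all 13 stress-response genes (exact p 0.00035) fell. Examples are Insig1 (10.3-fold), the oxygen sensor Egln3 (49.9-fold), the citrate synthase gene Cs (3.56-fold) and the chaperone Hspa5 (4.81-fold). The fatty acid receptor Ffar4 was at 0 reads against 19.9 ± 2.48 CPM, at least 490-fold lower.

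Interferon, progenitor, matrix and contractile genes were higher in J7_MLKL than in J7_CTL. Interferon genes rose in 20 of 21 (Fisher exact adjusted p 0.000172): Mx1 was 149-fold, Oasl2 112-fold, Ifit1 108-fold (34.8 ± 5.63 against 0.320 ± 0.0827 CPM, SD, n = 3) and Ifit3 62.2-fold higher. All 11 progenitor genes rose (exact p 0.00343), with the growth factor receptors Pdgfra 8.84-fold and Pdgfrb 6.84-fold and Zfp521, a repressor of adipogenesis, 5.57-fold higher. Matrix genes rose in 16 of 20 (exact p 0.0268), with the proteoglycan Dcn 13.5-fold, Lox 7.92-fold and Postn 7.21-fold higher. Contractile genes rose in 13 of 14 (exact p 0.0058), with Acta2 38.1-fold, Thbs1 20.4-fold and Cyr61 15.0-fold higher. All 6 tested Wnt ligands were called higher (exact p 0.0649, and 0.0333 without the filter), with Wnt6 148-fold (more without J7_CTL 2 and less without J7_CTL 3), Wnt4 7.24-fold and Wnt5a 3.5-fold higher. The chemokine Ccl2 rose 36.1-fold, the macrophage growth factor Csf1 14-fold and Gsdmd, the pore former of pyroptosis, 26.7-fold, with 8 NF-kB targets higher and 4 lower (exact p 0.574) and 6 apoptosis genes higher and 3 lower (exact p 0.606). Col15a1 fell 36.7-fold and Col18a1 6.37-fold, with 0 basement membrane genes higher and 4 lower (exact p 0.104). The epithelial keratin genes Krt18 and Krt8 fell 43.7-fold (more without J7_MLKL 3) and 23.7-fold, with all 4 tested epithelial markers lower (exact p 0.104). Cell cycle had 4 higher and 5 lower (exact p 0.8). By edgeR, 6893 of 7263 tested genes were called, 3522 higher and 3371 lower, and the authors listed 7288. The library J7_MLKL 3 stood apart and lay above both other J7_MLKL libraries in 19 of 22 adipocyte markers (Fabp4 reached 9.25, 11.3 and 25.9% of the CTL rise in J7_MLKL 1, 2 and 3), and without it 23 markers were lower than in J7_CTL. The median excess of these markers in J7_MLKL 3 was 0.993 (log2), and 0.594 after a trend on gene length and GC content was removed. Total reads in place of TMM moved the median log2 fold change by -0.103. Adjusted over the list alone, 8 immediate early genes were called in place of 9.

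**Figure D3:**
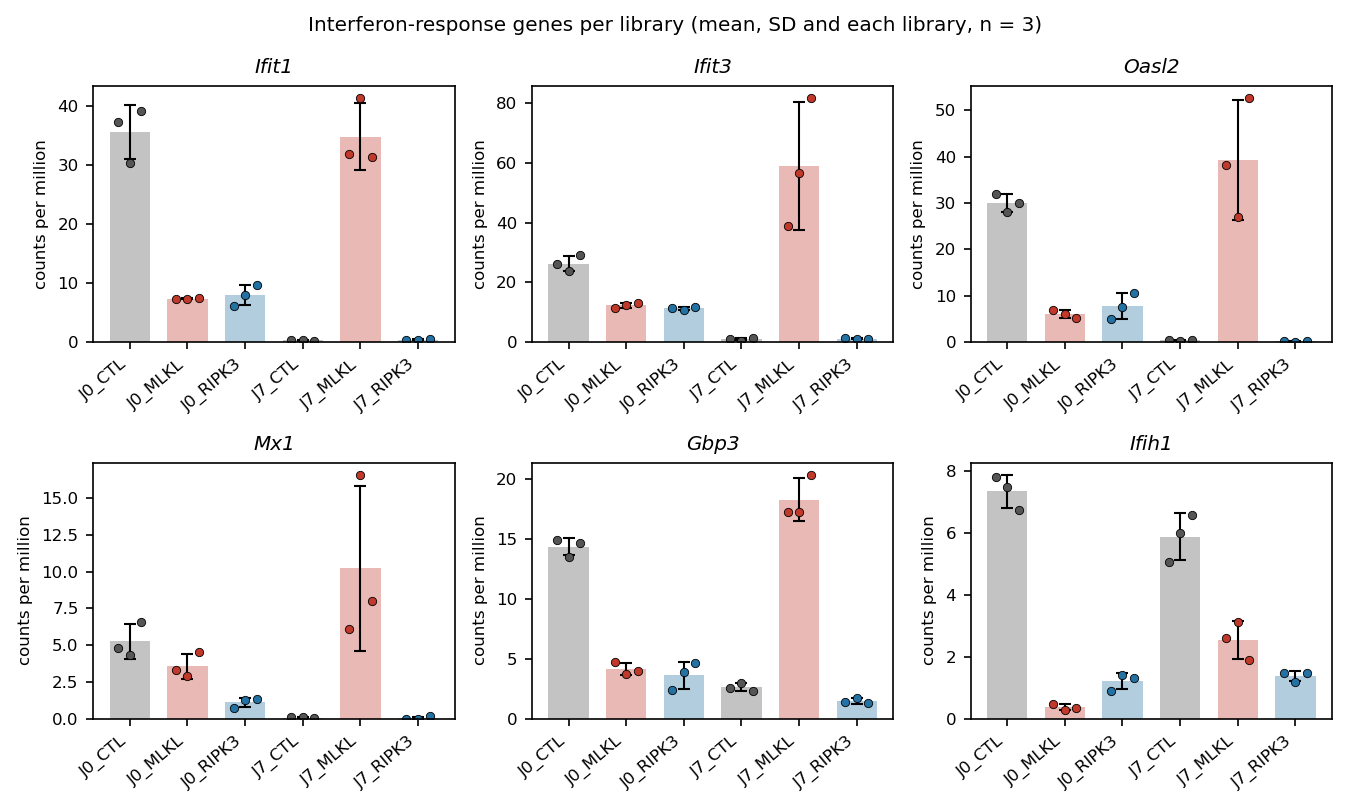
CPM of 6 interferon-response genes in each library, with bars for group means, error bars for the SD and points for the 3 libraries of a group. Ifit1 is at 35.5 in J0_CTL and 0.320 in J7_CTL, and at 7.36 in J0_MLKL and 34.8 in J7_MLKL.

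The comparison of J7_RIPK3 with J7_CTL asks how differentiated RIPK3-/- cells differed from differentiated control cells. Adipoq stood at 1791 ± 106 against 1756 ± 60.6 CPM (SD, n = 3, adjusted p 0.341, called higher without J7_RIPK3 3), Cebpa at 382 against 397 (adjusted p 0.352), and Pparg fell 1.33-fold (adjusted p 1.77e-09). Lipid synthesis rose in 15 of 16 members (Fisher exact adjusted p 0.00529), with the glucose-sensing factor Mlxipl 24.6-fold, Dgat2 3.38-fold and Agpat2, an acyltransferase of triglyceride synthesis, 1.96-fold higher, while droplet genes had 7 higher and 3 lower of 14 tested (exact p 0.56). Adipocyte markers rose in 17 of 24 (exact p 0.0158), with the carbonic anhydrase gene Car3 17.4-fold and Pck1 7.2-fold higher. Fatty acid oxidation rose in 13 of 15 (exact p 0.014), with Ppargc1a 2.91-fold, Acaa2 2.05-fold and Hadhb 1.76-fold higher, and respiratory genes in 18 of 20 (exact p 0.000116), with Cox6a1 1.53-fold and Cs 1.4-fold higher. All 7 brown and thermogenic genes were called higher (exact p 0.0604, 0.0248 with total reads only, and 0.03, 0.0439 and 0.0483 without J7_RIPK3 1, 2 and 3 in turn), led by Cidea, 26.2-fold higher at 65.1 ± 6.53 against 2.46 ± 0.361 CPM, with Cox8b 6.71-fold and Elovl3 3.49-fold higher. Cell cycle fell in 23 of 26 (exact p 3.51e-06), with the anaphase activator Cdc20 2.12-fold, Mki67 1.8-fold and Top2a 1.79-fold lower. Matrix fell in 16 of 21 (exact p 0.0343, and 0.0519 without the filter), with the microfibril gene Fbn1 2.22-fold and Col1a2 1.74-fold lower, and of the basement membrane genes Col15a1 fell 5.28-fold and Nid2 4.04-fold (7 lower and 2 higher, exact p 0.241).

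Contractile genes had 0 higher and 7 lower of 11 tested in J7_RIPK3 against J7_CTL (Fisher exact adjusted p 0.0343), with the actin crosslinker Flna 1.58-fold lower and Acta2 1.55-fold lower. This call was lost with total reads only (0.0519), with the authors' size factors (0.0609), without the filter (0.155) and with all 6 groups in 1 fit. It was also lost without J7_CTL 1 (0.155), J7_CTL 2 (0.11), J7_CTL 3 (0.11) or J7_RIPK3 1 (0.277). With an absolute log2 fold change over 1, 4 of 24 adipocyte markers, 3 of 16 lipid synthesis genes, 1 of 26 cell cycle genes and 0 respiratory and contractile genes stayed called, and none of the 7 lists that had passed did so. Cyp51 rose 4.64-fold, with 7 cholesterol genes higher and 1 lower (exact p 0.167), and glycolysis had 9 higher and 1 lower (exact p 0.0737, 0.034 with total reads only, 0.0173 without J7_CTL 2, 0.0172 without J7_RIPK3 2 and 0.01 without J7_RIPK3 3). NF-kB targets had 7 higher and 1 lower (exact p 0.167, and 0.0439 without J7_RIPK3 2). Interferon genes had 2 higher and 6 lower (exact p 0.347), with Ifih1 4.26-fold lower. Mdm2 rose 1.95-fold and the stress hormone gene Gdf15 3.33-fold, with 8 p53 targets higher and 1 lower (exact p 0.11, and 0.0193, 0.0439 and 0.0402 without J7_RIPK3 1, 2 and 3 in turn). Krt8 fell 7.14-fold, Thy1 2.86-fold and Dmd 10.3-fold, and Adcy1 was at 0 reads against 7.54 ± 0.748 CPM (SD, n = 3), at least 177-fold lower. By edgeR, 6600 of 11170 tested genes were called, 3302 higher and 3298 lower (3096 and 3396 with total reads only), beside 5696 listed by the authors. With p-values adjusted over the list alone, droplet genes had 11 called in place of 10, insulin signalling 7 in place of 6, necroptosis machinery 7 in place of 6 and glycolysis 11 in place of 10.

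**Figure D4:**
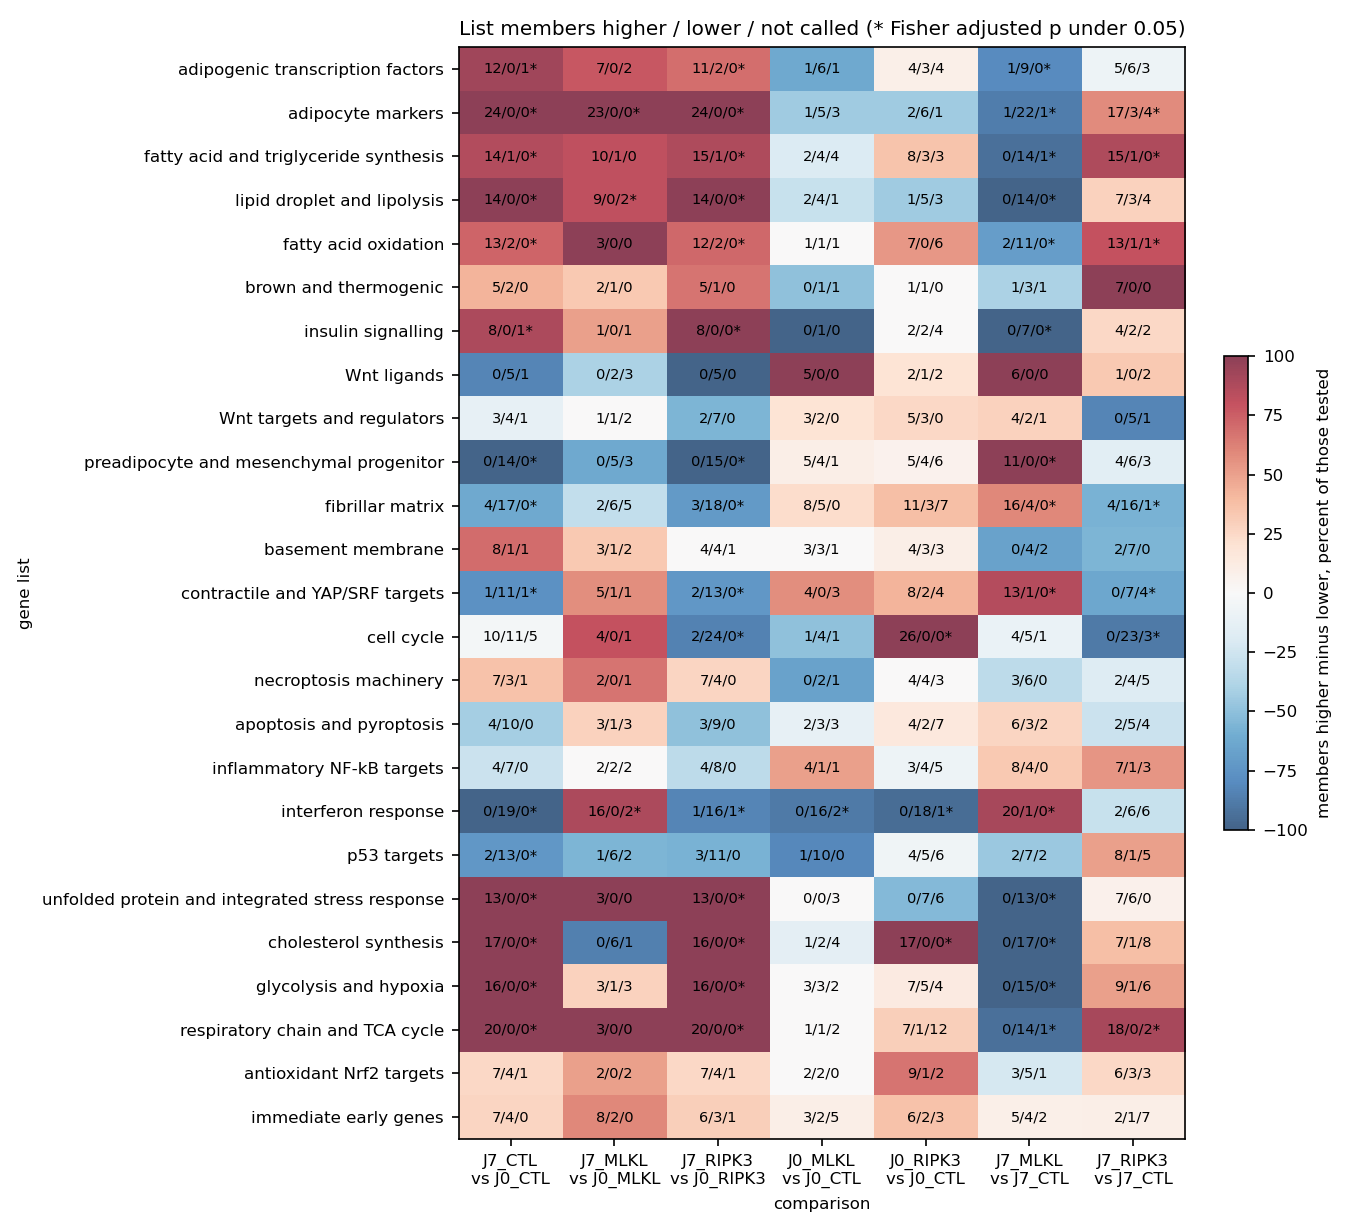
For each gene list (vertical axis) and comparison (horizontal axis), the cell gives members higher, lower and not called, and the colour gives members higher minus members lower as a percent of those tested. Cell cycle has 26 higher in J0_RIPK3 against J0_CTL and 23 lower in J7_RIPK3 against J7_CTL.

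The direct contrast of J7_MLKL with J7_RIPK3 asks how both knockouts differed from each other after differentiation. Adipoq was 3.8-fold lower in J7_MLKL (463 ± 194 against 1791 ± 106 CPM, SD, n = 3), Cidea 1200-fold lower, Pck1 161-fold lower and Dgat2 38.1-fold lower. Pparg was 5.16-fold lower (log2 -2.20 ± 0.19 SE) and Cebpa 10.6-fold lower. Oasl2 was 257-fold, Ifit1 78.4-fold, Acta2 59.1-fold and Gata2 17.5-fold higher in J7_MLKL. Adipocyte markers were lower in 23 of 24 (Fisher exact adjusted p 1.63e-06), lipid synthesis in all 16 (exact p 8.92e-05), droplet genes in all 14 (exact p 0.000164), cholesterol genes in all 16 (exact p 8.92e-05) and oxidation genes in 10 of 12 (exact p 0.00211). Insulin signalling was lower in 6 of 7 (exact p 0.0275, and 0.0568 with total reads only), and adipogenic factors in 9 of 10 (exact p 0.022). Glycolysis (15 of 15, exact p 0.000111), respiratory chain (14 of 15, exact p 0.000164) and stress response (12 of 13, exact p 0.000615) were lower too. Interferon genes were higher in 17 of 18 (exact p 0.000111), matrix genes in 16 of 20 (exact p 0.000996), progenitor genes in all 11 (exact p 0.00278) and contractile genes in 13 of 14 (exact p 0.00483). Ripk3 stood at 9.23 against 10.9 CPM (adjusted p 0.784, called lower without J7_MLKL 3). Apoptosis genes (exact p 0.0593), Wnt ligands and Wnt targets (exact p 0.0995 each) were higher in those called and passed with total reads only (exact p 0.0461 each), and 5 brown genes were lower (exact p 0.0531, and 0.0253 at an absolute log2 fold change over 1). By edgeR, 5723 of 6591 tested genes were called, 2952 higher and 2771 lower, and total reads in place of TMM turned this to 2801 higher and 3073 lower and moved the median log2 fold change by -0.171. When adjusted over the list alone, each list had the same number called.

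The direct contrast of J0_MLKL with J0_RIPK3 asks the same before differentiation. Fabp4 was 6.9-fold and Cebpa 2.66-fold lower in J0_MLKL (1.26 ± 0.326 against 8.76 ± 0.884 CPM for Fabp4, SD, n = 3). The cyclin Ccne1 was 3.77-fold and the checkpoint kinase Bub1 3.81-fold lower. The small GTPase gene Rab12 was 40.8-fold and Timp3 28.0-fold lower, and Chrdl1 was 23.2-fold higher. Cell cycle (0 higher, 6 lower), cholesterol (0 higher, 7 lower) and NF-kB targets (5 higher, 0 lower) each had a Fisher exact adjusted p of 0.225, and no list passed the test. By edgeR, 2297 of 3455 tested genes were called, 1144 higher and 1153 lower. Adjusted over the list alone, adipocyte markers had 4 called in place of 5 and droplet genes 2 in place of 3.

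Whether the J7 minus J0 change itself differed between MLKL-/- and CTL cells was tested on genes with counts in all 4 groups. All 18 tested interferon genes had a higher J7 minus J0 change in MLKL-/- cells (Fisher exact adjusted p 0.00336): Oasl2 differed by 9.03 ± 0.41 and Ifit1 by 8.99 ± 0.26 (log2, SE, n = 3 per group). The rise of Pparg was smaller by a log2 difference of -2.45 ± 0.21 (adjusted p 1.41e-06) and that of Cebpa by -2.93 ± 0.27 (adjusted p 2.35e-06). Lipid synthesis had 0 higher and 9 lower (exact p 0.0039), with Scd1 at -4.20 and Dgat2 at -2.89, and droplet genes 0 higher and 8 lower (exact p 0.0065), with the monoglyceride lipase gene Mgll at -6.30. Adipocyte markers had 1 higher and 8 lower of 24 (exact p 0.0188), with the lipoprotein lipase gene Lpl at -2.76, while Fabp4 was at -0.46 (adjusted p 0.463) and was called lower without J7_MLKL 3. The marker result was lost without J0_CTL 1 (exact p 0.0791) and without J7_MLKL 1 (exact p 0.0535). Without both libraries that stand apart, J0_MLKL 2 and J7_MLKL 3, markers had 0 higher and 13 lower (exact p 0.000239). Adipogenic factors (1 higher and 8 lower) and basement membrane (0 and 6) then passed too (exact p 0.0165 for each, against 0.0721 and 0.084 with all libraries). The factors also passed without J0_CTL 3 (0.0326), J0_MLKL 1 (0.034) or J7_MLKL 2 (0.039), and basement membrane without J0_MLKL 2 (0.0397), J7_MLKL 1 (0.0408), J7_MLKL 2 (0.0402) or J7_MLKL 3 (0.046). Matrix had 12 higher and 1 lower (exact p 0.0721, 0.0379 with DESeq2 size factors, 0.0277 with a mean of at least 50 counts, 0.0343 with all 6 groups in 1 fit and 0.0375 without J7_MLKL 1), and progenitor genes 7 higher and 0 lower (exact p 0.134, and 0.0379 with DESeq2 size factors). Cholesterol genes and glycolysis genes each had 0 higher and 7 lower (exact p 0.00974), with Hmgcs1 at -2.90 and Hk2 at -3.52, and both were lost with DESeq2 size factors (exact p 0.0568). By edgeR, 1981 of 3033 tested genes were called, 1184 higher and 797 lower, while DESeq2 size factors gave 963 higher and 1012 lower (48.8 in place of 59.8% higher) and moved the median by -0.316. With p-values adjusted over the list alone, adipogenic factors had 8 called in place of 7, adipocyte markers 8 in place of 9, basement membrane 5 in place of 4 and p53 targets 3 in place of 5.

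The same difference was tested for RIPK3-/- cells. All 26 cell cycle genes had a lower J7 minus J0 change than in CTL, where 10 rose and 11 fell (Fisher exact adjusted p 1.89e-06): Cdc20 differed by -2.18 ± 0.10, Mki67 by -2.18 ± 0.09 and Top2a by -2.09 (log2, SE, n = 3 per group). Matrix had 0 higher and 17 lower of 21 (exact p 0.000334), with Col3a1 at -1.03 and Postn at -0.98. Basement membrane had 0 higher and 8 lower (exact p 0.0328, and 0.0791 with total reads only), with Nid2 at -1.32, and contractile genes 0 higher and 9 lower (exact p 0.0191, and 0.0546 with total reads only), with Acta2 at -0.97. Fatty acid oxidation had 12 higher and 0 lower (exact p 0.00124), with Ppargc1a at 1.20 and Acaa2 at 0.79, and respiratory chain 13 higher and 1 lower (exact p 0.00355), with Cox6a1 at 0.45. Interferon genes had 11 higher and 0 lower (exact p 0.00197), with Ifit1 at 2.64 and Gbp2 at 1.83, and cholesterol genes 1 higher and 14 lower (exact p 0.00623), with Idi1 at -0.90. Pparg differed by -0.62 and Cebpa by -0.87, and Dgat2 by 2.09. Wnt targets and regulators had 0 higher and 7 lower (exact p 0.0572, 0.0119 with DESeq2 size factors and 0.0485 without J0_CTL 3), p53 targets 7 higher and 1 lower (exact p 0.0793, 0.0354 with total reads only and 0.0268 without J0_RIPK3 3), glycolysis 7 higher and 1 lower (exact p 0.0793, and 0.029 without J7_RIPK3 3) and lipid synthesis 9 higher and 3 lower (exact p 0.176, 0.0355 without J0_CTL 3 and 0.0303 without J7_RIPK3 2). By edgeR, 4298 of 11027 tested genes were called, 2028 higher and 2270 lower, while DESeq2 size factors gave 2481 higher and 1950 lower (56 in place of 47.2% higher) and total reads 1665 and 2534. When adjusted over the list alone, matrix had 19 called in place of 17, respiratory chain 16 in place of 14 and stress response 12 in place of 10. Droplet genes had 8 in place of 7, antioxidant genes 8 in place of 7, insulin signalling 6 in place of 5, brown genes 4 in place of 3 and chondrocyte markers 2 in place of 1.

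Effects of both knockouts against the same controls were compared across genes. At J0, Adcy1 fell by -6.67 in MLKL-/- and -6.85 in RIPK3-/- cells on the log2 scale, and Kcnc2 rose by 6.05 and 3.85. Ifih1 fell by -4.29 and -2.61. Of 3458 genes, 669 were higher in both (445.9 if independent) and 768 lower in both (472.6 if independent), and 451 went opposite ways. The correlation was 0.585, against 0.405 (0.335 to 0.432) in 20 simulated draws of unchanged groups, and the covariance 0.514 against 0.00741. The draws hold no knockout effects, so their correlations are of noise around shared controls alone. They are no chance level for the correlation of real effects. At J7, Dgat2 went opposite ways, by 1.78 in RIPK3-/- and -3.41 in MLKL-/- cells. Of 6284 genes, 611 were higher in both (807.8 if independent), 906 lower in both (948.5 if independent) and 2000 opposite. The J7 correlation was -0.0134 against 0.306 (0.272 to 0.345) simulated, and the covariance -0.0152 against 0.00826. Without the filter the J7 correlation was 0.0169. It was 0.00108 without J7_CTL 1 and 0.0049 without J7_CTL 3. The 3 control libraries cannot be divided into 2 groups of 2, so part of any agreement may come from shared controls. By covariance that simulated part was small at J0 (0.00741 against 0.514). Genes are not independent replicates.

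Fold changes of knockout against control also differed by chromosome, a pattern looked at after the values were seen. In RIPK3-/- cells the median log2 fold change of chromosome 5 genes was 0.27 at J0 and 0.398 at J7, and that of chromosome 18 genes 0.203 and 0.306. Chromosome 6 had medians of -0.06 at J0 and -0.212 at J7, and chromosome 8 of 0.111 and 0.046. On chromosome 14, genes before Ripk3 had medians of -0.023 at J0 and -0.02 at J7, and genes after it -0.224 and -0.424. After Ripk3, 103 of 143 genes were called lower at J0 and 132 of 151 at J7. Ripk3 itself fell by -0.73 at J7, and Cyp51, 2.86-fold higher at J0 and 4.64-fold higher at J7, lies on chromosome 5. In MLKL-/- cells, the median of chromosome 8 genes, which include Mlkl, was 0.464 at J0 and 0.714 at J7, and that of chromosome 18 genes -0.397 and -0.575. Others did not keep 1 sign: the median of chromosome 11 genes was 0.312 at J0 and -0.259 at J7, and that of chromosome 19 genes 0.332 and -0.412. In J7_MLKL the first and last part of chromosome 1 had medians of -0.308 and 0.56 (exact p 0.0973 for its calls) and those of chromosome 10 -0.335 and 0.608. Because these tables list called genes only, MLKL medians are larger than those of all genes would be. Few of these genes lie near 0, so a small excess of calls sets the sign of a median. At J7_MLKL, calls were 224 higher and 235 lower on chromosome 11 and 78 and 95 on chromosome 19. They were 165 and 152 on chromosome 1 and 127 and 118 on chromosome 10. The changes of sign therefore do not show a reversal on these chromosomes.

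**Figure D5:**
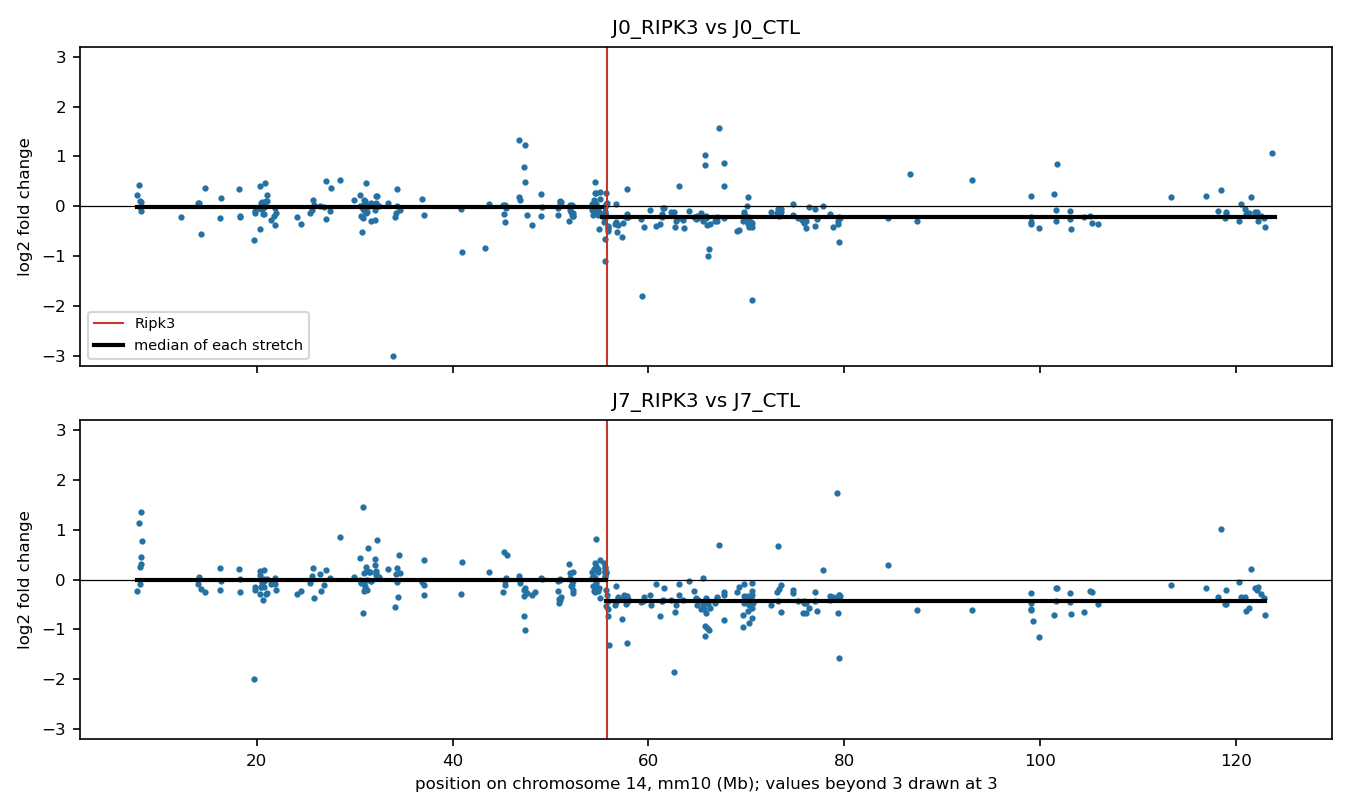
Log2 fold change (vertical axis) of each tested gene by position on chromosome 14 (horizontal axis, mm10, Mb) for J0_RIPK3 against J0_CTL and J7_RIPK3 against J7_CTL, with black lines for the medians of the stretches before and after the position that best parts them and a red line at Ripk3. The stretch after that position has a median of -0.219 at J0 and -0.421 at J7.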

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

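Of the tests in this part, all except those of the J7 minus J0 changes, of the sample splits, of further differentiation in J7_MLKL replicate 3 and of the marker decrease without that library were chosen after the results were seen. Groups of 3 libraries were not tested for outliers.

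The J7 minus J0 change of 1981 genes, of 3033 tested, differed between MLKL-/- and CTL cells by a test of the difference itself. The tested genes had been preselected on comparisons of the same libraries, and p-values were adjusted over them alone. The adjusted p therefore does not give the error rate over all genes. Called members by list were 18 for interferon response (Ifit1 at 8.99, log2), 9 for adipocyte markers, 9 for fatty acid and triglyceride synthesis, 8 for lipid droplet and lipolysis, 7 for cholesterol synthesis and 7 for glycolysis and hypoxia. Of 100 drawn splits of the 12 libraries, 6 gave as many genes with the real one included. The highest other split gave 2480 genes and exchanged the genotype labels at J0. All 6 left the J7 groups whole and so kept the J7 difference between genotypes, which leaves chance in the change itself untested.

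The J7 minus J0 change of 4298 genes, of 11027 tested, differed between RIPK3-/- and CTL cells by the same test, with the same limit from preselection. Called members by list were 26 for cell cycle (Mki67 at -2.18, log2), 17 for fibrillar matrix, 15 for cholesterol synthesis, 14 for respiratory chain and TCA cycle, 12 for fatty acid oxidation, 11 for interferon response, 9 for contractile and YAP/SRF targets and 8 for basement membrane. Of 100 drawn splits, 2 gave as many genes with the real one included. The other was the exchange of the genotype labels at J0 (5974 genes), which also left the J7 groups whole. Splits within a stage mix the genotypes and respond to any difference between them, so here too chance in the change itself is left untested.

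For the 9 comparisons of 2 groups, the 10 possible splits are too few for a share under 0.05. The genes had also been preselected for differences between groups, which other splits turn into spread within a group. Low counts in other splits were thus set in advance and do not test chance. In each, 1 split, the real one, gave as many genes, and the highest other gave 0: 11555 genes for J7_CTL against J0_CTL, 2051 for J7_MLKL against J0_MLKL, 11533 for J7_RIPK3 against J0_RIPK3, 3196 for J0_MLKL against J0_CTL, 6159 for J0_RIPK3 against J0_CTL, 6893 for J7_MLKL against J7_CTL, 6600 for J7_RIPK3 against J7_CTL, 5723 for J7_MLKL against J7_RIPK3 and 2297 for J0_MLKL against J0_RIPK3.

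J0_MLKL replicate 2 and J7_MLKL replicate 3 stood apart from the other libraries of their groups (chi-squared per degree of freedom of pairs 51.0 and 58.2, and 237 and 225, against 2.81 to 6.16 for other pairs). Their deviations from the group mates fell with gene length (Spearman -0.577 and -0.576), so long genes tended to be read less. When a trend on gene length and GC content was removed, the SD of deviations (log2) went from 0.358 to 0.281 in J0_MLKL replicate 2. It went from 0.678 to 0.546 in J7_MLKL replicate 3, against at most 0.138 before removal outside the MLKL groups. The trend thus left most of the spread. The first form of this test, the share of variance explained, fell between its bounds and was replaced after its result. That share was 38.4% in J0_MLKL replicate 2 and 34.3% in J7_MLKL replicate 3. The SD after removal follows from it and is no second test. Gene length and GC content as the whole cause therefore stay open, since trends of other forms were not tested. Further differentiation of J7_MLKL replicate 3 stays open (r 0.183 with the CTL change, between the bounds set before). A property shared by both libraries may be the cause (r 0.856 over 973 genes that changed by less than 2-fold in CTL), and a biological difference between cultures was not tested.

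Adipocyte markers were lower in J7_MLKL than in J7_CTL, which would follow if a single share of the cells had differentiated like J7_CTL. The shares of the CTL rise, as means of J7_MLKL replicates 1 and 2, ran from 3.65 to 27.72% over 22 markers (highest over lowest 7.59), which argues against a single share. In replicate 3, not part of that test, they ran from 4.94 to 66.91%. Exchanged labels of J7_MLKL and J7_RIPK3 are argued against by the MLKL minus RIPK3 difference, which correlated at 0.609 between J0 and J7 over 909 genes that changed by less than 2-fold in CTL and at 0.387 over all 2505 genes. The library that stands apart is not the source, since it lay above both other libraries in 19 of 22 markers. Leaving it out was thus bound to deepen most decreases, and 23 markers were called lower without it and 22 with it. An effect of the genotype may remain as a hypothesis. It cannot be told apart from other differences between the cell lines, whose fold changes also differed by chromosome. Clonal differences as a cause of the marker decrease were not tested.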

How the results depend on the processing

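The authors' size factors, the authors' number of tested genes and the fits without both MLKL libraries that stand apart were tests chosen after the data were seen. For the gene lists, so were total reads only, no filter, the DESeq2 Wald test and the fold limit, which were fixed before for counts and named genes alone. Of the alternative values of counts and summaries, 217 were labelled the same, 18 weaker and 3 turned. For counts of genes, this label compares the size of the count and not the direction of the calls. For example, the MLKL difference of changes was labelled the same with DESeq2 size factors. It went there from 1184 higher and 797 lower to 963 higher and 1012 lower. The 3 that turned were values of the J7 correlation of both knockouts' effects. For named genes, 23987 were the same, 348 stronger, 728 weaker and 14 turned.

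With all 6 groups in 1 fit, only the 2802 genes with counts in all libraries are tested. Counts fell to 2511 (J7_CTL against J0_CTL), 2589 (J7_RIPK3 against J0_RIPK3), 1992 (J0_MLKL against J0_CTL), 957 (J0_RIPK3 against J0_CTL), 2536 (J7_MLKL against J7_CTL), 1136 (J7_RIPK3 against J7_CTL), 2473 (J7_MLKL against J7_RIPK3) and 642 (RIPK3 difference of changes). J7_MLKL against J0_MLKL rose to 2147, the MLKL difference of changes was at 1976 and J0_MLKL against J0_RIPK3 at 1664, and 51 list tests passed in place of 86. This fit tests few members of many lists, for example 5 of 26 cell cycle genes. Calls lost in J0_RIPK3 against J0_CTL were cell cycle (0.281) and cholesterol (0.237), and in J7_RIPK3 against J7_CTL cell cycle, oxidation, matrix, respiratory chain (0.482 each) and contractile genes (1). In the RIPK3 difference of changes they were cell cycle, contractile, oxidation (0.484 each), matrix (10 lower of 13, 0.0885), respiratory chain (0.355), cholesterol (0.627) and basement membrane (1). Contractile, oxidation, insulin signalling, respiratory chain and stress-response calls were lost in J7_CTL against J0_CTL, J7_RIPK3 against J0_RIPK3, J7_MLKL against J7_CTL and J7_MLKL against J7_RIPK3 (0.112 to 0.358). The others were p53 targets in J7_CTL against J0_CTL (0.219), cell cycle in J7_RIPK3 against J0_RIPK3 (1) and droplet genes in J7_MLKL against J0_MLKL (0.0782).

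An absolute log2 fold change over 1 left 5203 (J7_CTL against J0_CTL), 1173 (J7_MLKL against J0_MLKL), 5591 (J7_RIPK3 against J0_RIPK3), 999 (J0_MLKL against J0_CTL), 646 (J0_RIPK3 against J0_CTL), 4336 (J7_MLKL against J7_CTL), 718 (J7_RIPK3 against J7_CTL), 617 (J0_MLKL against J0_RIPK3) and 598 (RIPK3 difference of changes), by its own construction. With this limit 12 list calls were lost, and 4 lists had 0 members left: respiratory chain and contractile genes in J7_RIPK3 against J7_CTL, and respiratory chain and cholesterol genes in the RIPK3 difference of changes. In J7_RIPK3 against J7_CTL the calls lost were adipocyte markers (4 of 24 left, exact p 0.684), lipid synthesis (3 of 16, 0.684), oxidation (2 higher and 1 lower, 1), cell cycle (1 of 26, 0.794) and matrix (2 of 21, 0.684). In the RIPK3 difference of changes those lost were basement membrane, contractile, oxidation and matrix genes. The others were p53 targets in J7_CTL against J0_CTL (exact p 0.315), droplet genes in J7_MLKL against J0_MLKL (exact p 0.12) and cholesterol genes in J0_RIPK3 against J0_CTL (exact p 0.842).

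The J7 correlation of both knockouts' effects (-0.0134) became 0.0169 without the filter, and leaving out 1 library gave -0.0246 to 0.0049, above 0 without J7_CTL replicate 1 (0.00108) and J7_CTL replicate 3 (0.0049). The cause was not tested.

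Named genes that turned were Jun in J7_RIPK3 against J0_RIPK3 (0.172), Acacb (-0.248) and Mcl1 (-0.19) in J7_MLKL against J7_CTL with all 6 groups in 1 fit, and Mcl1 in the MLKL difference of changes with DESeq2 size factors (-0.266). Leaving out 1 library gave -0.224 (without J0_MLKL replicate 2) to 0.2 for Pnpla2 in J0_MLKL vs J0_CTL and -0.082 (without J0_MLKL replicate 2) to 0.121 for Hmox1 in J0_MLKL vs J0_RIPK3. It gave -0.78 (without J7_MLKL replicate 3) to 1.101 for Cox8b in J7_MLKL vs J7_CTL, -0.343 to 0.156 (without J7_MLKL replicate 3) for Col6a3 in J7_MLKL vs J7_RIPK3 and -0.226 to 0.312 (without J7_MLKL replicate 3) for Eda2r in J7_MLKL vs J7_RIPK3. Without both libraries that stand apart, each of these 5 had the turned value. Fabp4 in MLKL difference in the J7 minus J0 change went from -0.455 to -1.049 without J7_MLKL replicate 3 and was then called. Without that library Fabp4 in J7_MLKL vs J0_MLKL went from 9.881 to 9.275, Fabp4 in J7_MLKL vs J7_CTL from -2.584 to -3.212, Krt18 in J7_MLKL vs J7_CTL from -5.345 to -6.209 and Ripk3 in J7_MLKL vs J7_RIPK3 from -0.064 to -0.33. Wnt6 in J7_MLKL vs J7_CTL went from 7.173 to 8.664 without J7_CTL replicate 2 and 6.547 without J7_CTL replicate 3, and Adcy1 in J0_RIPK3 vs J0_CTL from -6.851 to -7.867 without J0_RIPK3 replicate 3. Pparg in J0_MLKL vs J0_CTL went from -0.339 to -0.225 without J0_MLKL replicate 3, -0.314 without J0_CTL replicate 2 and -0.352 without J0_CTL replicate 3. Mx1 in J0_MLKL vs J0_CTL went from -0.521 to -0.639 without J0_CTL replicate 2 and -0.733 without J0_MLKL replicate 3, and Adipoq in J7_RIPK3 vs J7_CTL from 0.042 to 0.079 without J7_RIPK3 replicate 3. The causes were not tested.

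With the replicate block, J7_MLKL against J0_MLKL had 1734 genes and J7_CTL against J0_CTL 11551. Adjustment over the authors' number of tested genes left 1440 of 2051 genes in J7_MLKL against J0_MLKL and 2768 of 3196 in J0_MLKL against J0_CTL. It left 6247 of 6893 in J7_MLKL against J7_CTL, 5842 of 6159 in J0_RIPK3 against J0_CTL and 6275 of 6600 in J7_RIPK3 against J7_CTL. Leaving out 1 library or both libraries that stand apart moved no count of genes past 1.5 times its value, for example 1785 to 2546 in J7_MLKL against J0_MLKL. A library left alone with 1 other in its group is assumed to vary like the other groups. The pseudocount alternative did not apply to counts, and set tests with an estimated correlation were not run, because the tables are preselected. Planted 2-fold changes were found in 38% of simulated cases in J7_MLKL against J7_CTL. The simulation called 71 of 7161 genes and the real test 6893 of 7263, so the simulated adjustment was stricter. The 38% is thus not the detection rate of the real test, and an uncalled gene is still not shown to be unchanged.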

Other observations

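The tests in this part were chosen after the results were seen. The authors' pathway tables were read as lists of the genes the authors called. In J7_RIPK3 against J7_CTL, their fatty acid metabolism pathway held 42 higher and 4 lower genes (authors' adjusted p 4.77e-07) and valine, leucine and isoleucine degradation 34 and 5 (authors' adjusted p 1.6e-06). In J7_MLKL against J7_CTL, fatty acid metabolism held 5 higher and 42 lower genes (authors' adjusted p 5.02e-06) and the citrate cycle 2 and 28 (authors' adjusted p 4.62e-08). In J0_RIPK3 against J0_CTL, DNA replication held 28 higher and 0 lower genes (authors' adjusted p 3.28e-05).

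Genes changed by over 2-fold in both knockouts were counted at each stage. At J0, 79 were higher in both and 154 lower in both, with 12 and 5 opposite. At J7, 76 were higher in both and 117 lower in both, with 79 and 83 opposite.

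Median log2 fold changes of knockout against control differed between chromosomes. Chance arrangement is argued against (p 0.0001 in all 4 comparisons, the smallest that 10000 shuffles can give). In RIPK3-/- cells, a length and GC trend removed at most 2.9% of the variance of chromosome medians. For MLKL-/- cells it removed 19.9% at J0 and 21.4% at J7. These shares fell between the bounds of the first form of the test, which was replaced after its result. The replacement was the shuffle p after removal, which stayed at 0.0001. With most of the variance left and the same p before removal, that outcome was nearly settled in advance. It therefore does not weigh against length and GC content in MLKL-/- cells. Chromosome copy number of the cell line may be the cause in RIPK3-/- cells, since medians at J0 and J7 correlated at 0.935 over 20 chromosomes. The MLKL-/- correlation was 0.875, from medians of more strongly preselected genes. The size of a shift was not always kept between stages. In RIPK3-/- cells the median of chromosome 6 was -0.06 at J0 and -0.212 at J7. Medians of the first and last parts of chromosomes correlated at 0.846 in J0_MLKL, 0.704 in J7_MLKL, 0.836 in J0_RIPK3 and 0.826 in J7_RIPK3. Medians had opposite signs inside single chromosomes of J7_MLKL, such as -0.308 and 0.56 in the first and last part of chromosome 1. Few preselected genes lie near 0, and calls there were nearly balanced (165 higher and 152 lower). Such signs therefore cannot be weighed for or against a whole-chromosome copy number. The MLKL correlations, of stages and of chromosome parts, rest on the same medians and share this limit. Copy number in MLKL-/- cells thus stays open.

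On chromosome 14 in RIPK3-/- cells, the position that best parts the fold changes lay 0.31 Mb from Ripk3 at J0 and 0.15 Mb at J7. At J0 chromosome 14 ranked 3 of 20 chromosomes by how well 1 position parts it, and at J7 it ranked 1. A changed copy number from Ripk3 outward may explain the lower levels beyond Ripk3, and DNA copy number itself was not analysed here.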
